A study of Mus musculus with 12 samples.

How the data were processed

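The series comprises 12 samples of E14tg2a mouse embryonic stem cells (129SV background) with a stable cRAF-ErT2 cassette: 4 inputs and 8 ChIP libraries, from clones a and b at 0 h and after 2 h of 250 nM 4OHT, precipitated for MED1 or, through a FLAG tag, for MED24. Cells had been kept with 2 µM Chir99021 before the change to medium with PD173074, and chromatin was crosslinked with formaldehyde and disuccinimidyl glutarate, per the labels' protocols. Groups were taken from the sample titles. The inputs are not analysed here. The 4 groups with files hold 2 libraries each. No library without the RAF cassette and no vehicle-treated library was analysed here, so 4OHT, time and ERK activation go together in every comparison.

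The submitters' processing notes name Bowtie2, bedtools, MACS2 and the mm10 build; versions, settings and the role of the inputs are not given in the sources used here. Peaks were deposited per library, not on pooled samples. The MED1 lists have the narrowPeak layout, in which the deposited columns are a score, a fold enrichment (a ratio), and the −log10 p-value and −log10 q-value of each peak, as the authors' peak caller gave them, followed by the summit. In the MED1 lists the deposited score was 10 times the −log10 q, rounded down, in 100% of peaks. The MED24 lists give position, name and a score deposited by the authors, with no fold, p or summit; this score was read as 10 times −log10 q, as in the MED1 lists, which the MED24 lists themselves do not state. The lowest score was 20 in each of the 8 lists. Peak names in the MED24 lists carry a FLAG tag and a folder name of another cofactor, EP300, while the labels say MED24; the labels were followed. Every such value per peak is the authors' own and was used only to rank or filter peaks within a list. No peak list gives read numbers, so depth is unknown and no interval that needs it is given. What limits precision is the number of clones, 2 per group.

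From the lists, peaks on chromosomes 1 to 19, X and Y were merged within each protein wherever they overlapped by at least 1 bp; no peak lay on another chromosome. A region counted as called in a library if a peak of that library fell in it, as gained if called in both 2 h libraries and neither 0 h library, as lost in the reverse case, and as retained if called in all 4. No test was made per region; instead the same counts were made for the other splits of the 4 libraries. Numbers of peaks and covered bases were compared by exact two-sided permutation tests. Overlap of MED1 and MED24, gene ends and clusters were tested with two-sided Fisher's exact tests over regions. Clusters joined regions over the stitching distance customary for super-enhancers, in all 4 libraries together, and the 200 with the most covered bases were taken.

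A region was assigned to the nearest protein-coding gene within 100 kb, from a RefSeq gene table of the GRCm38.p6 assembly, the build that mm10 stands for. The table gives the span of each of 21887 protein-coding genes used, without strand or exons. The plan had been to use the nearest transcription start site and promoters, which that table does not place, so distance to the gene span and a window of 1 kb around either gene end took their place. Of 65291 MED1 and 66123 MED24 regions, 91.6% and 90.7% were assigned. No genome sequence was used here, so the planned search for motifs was not run and no sequences are given.

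There were 14 gene lists with 210 genes, all 210 found in the gene table: naive pluripotency, core pluripotency, primitive endoderm, ERK immediate early, ERK feedback, formative epiblast, mesendoderm, neural, trophectoderm, fibroblast, Wnt target, LIF STAT3, estrogen receptor target and housekeeping. The net change of a list is gained minus lost regions as a percentage of its assigned regions. It was compared with 10000 random gene lists of the same size, matched gene by gene on the number of assigned regions, in a two-sided permutation test, with Benjamini-Hochberg adjustment over 28 tests (14 lists in each protein) and a threshold of 0.05. For the rank shift, retained regions were ranked within each library by −log10 p (MED1) or score (MED24), expressed as percentiles, and the 2 h minus 0 h difference was taken within each clone and averaged, with the same kind of permutation test and adjustment. Lists, tests, the rule for named genes and most alternatives were fixed before the data were examined.

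Named genes and regions follow that rule. Per protein these are the 5 gained and 5 lost regions with the best mean rank in the 2 libraries that call them, the 5 retained regions that rose and the 5 that fell most by the smaller of the shifts of the clones, the 5 genes with the most gained and the 5 with the most lost regions (leaving out symbols of Gm followed by digits or ending in Rik), and the 5 largest clusters. For each list they are up to 4 members with the largest gained minus lost count over both proteins, and for naive pluripotency, primitive endoderm and the ERK lists members with 0; not all of these are named, and some regions that the rule selects are not reported here. Fos, Gata6 and Fgf4 were picked from list members after their values were seen.

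Clone letters pair the libraries, since the labels give the same clone at both times. As a check, differences between clones at 0 h and at 2 h were compared across retained regions and showed r = -0.00505 for MED1 and -0.00686 for MED24. No clone difference kept from 0 h to 2 h was thus seen, and the pairing rests on the labels alone. Clone differences of MED1 were also correlated with those of MED24, across regions called in every library of both proteins. Within a time r was 0.246 (0 h) and 0.260 (2 h), but -0.00126 between MED1 at 0 h and MED24 at 2 h. The replicate block, counting within each clone, was an alternative for gained and lost regions, and the main choice for the rank shift. Other alternatives were stricter peaks (−log10 q of at least 5 or 10), the 10000 or 20000 highest ranked peaks of each library, windows of 250 bp around summits or midpoints, a cover of 50%, leaving out each clone and each library, assignment within 20 kb or to every gene within 50 kb, Fisher's exact test over regions, ranking by fold or peak length, the median shift (against 2000 random lists), wider gene-end windows, joining within 5 kb and the top 500 clusters. Assignment to the nearest gene end, and leaving out each clone for the overlap, location and clusters, were added after the data were seen.

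The procedure was tested on simulated data. In 4 simulated lists over the 20152 retained MED1 regions, each called with a probability of 97%, 95% of 200 planted gained and 92% of 200 planted lost regions were recovered, with 18 and 23 false ones. Calls were drawn independently, so these rates follow largely from the set probability and check only the counting. In the real lists the clones shared 65.1% (0 h) and 67.1% (2 h) of merged MED1 regions, so the rates do not carry over. For MED1, with 1000 random lists per test, 5.5% of 200 random lists of genes had unadjusted p under 0.05 after changes were shuffled over regions, and 80.5% did after a planted net change of 20 points. Shuffling removes any crowding of changes at the same genes, and the planted change was equal for every gene. These shares therefore do not carry over to the real lists or to adjusted p-values. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.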

Results

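Mediator occupancy was mapped by ChIP-seq in mouse embryonic stem cells of the E14tg2a line that stably carried a cRAF-ErT2 cassette. In such cells 4-hydroxytamoxifen (4OHT) switches on the RAF kinase and, through it, ERK signalling. Cells were held for 24 h in medium with serum, LIF and 250 nM of the FGF receptor inhibitor PD173074, and then either left untreated (0 h) or given 250 nM 4OHT for 2 h. Chromatin from clones a and b was precipitated for MED1, or with anti-FLAG for MED24; both proteins are subunits of Mediator, the complex that links enhancer-bound factors to RNA polymerase II. This gave 8 peak lists in 4 groups of 2 clones, and 4 input samples that are not analysed here. Peaks had been called in each library separately. Peak lists give no read numbers, so the depth behind each list is unknown.

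The first question was how many sites each library held. MED1 libraries held 38668 and 37483 peaks at 0 h in clones a and b, and 43949 and 47305 at 2 h. MED24 libraries held 41689 and 38398 peaks at 0 h, and 42445 and 48931 at 2 h. The mean number of MED1 peaks was 38076 ± 838 (SD, n = 2) at 0 h and 45627 ± 2373 (SD, n = 2) at 2 h, a difference of 5281 in clone a and 9822 in clone b. The MED24 means were 40044 ± 2327 and 45688 ± 4586 (SD, n = 2), with a difference of 756 in clone a and 10533 in clone b. The mean MED24 difference of 5645 was close to the SD between clones at 2 h. For the number of peaks of either protein the exact two-sided permutation test gave p = 0.333 (n = 2), the smallest p that 2 libraries against 2 can reach. The MED24 difference was 2401.5 without the 2 h library of clone b and 8887.5 without that of clone a. MED1 peaks covered 23.3 ± 0.542 Mb at 0 h and 26.1 ± 1.77 Mb at 2 h (SD, n = 2), a difference of 1.20 Mb in clone a and 4.48 Mb in clone b (exact permutation p = 0.333). MED24 peaks covered 21.8 ± 1.41 Mb and 24.5 ± 2.98 Mb (SD, n = 2), but the difference was -0.428 Mb in clone a and 5.79 Mb in clone b (exact permutation p = 0.667). Within a time, the clones shared 65.1% (0 h) and 67.1% (2 h) of the merged MED1 regions and 68.1% and 68.8% of the MED24 regions. Between times, the same clone shared 44.3% (clone a) and 43.6% (clone b) for MED1, and 46.0% and 45.3% for MED24.

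The main comparison asked where MED1 occupancy differed after 2 h of 4OHT. Of 65291 merged MED1 regions, 11484 were called in both clones at 2 h and in neither at 0 h (gained), 4508 were called in both at 0 h and in neither at 2 h (lost), and 20152 were called in all 4 libraries (retained). Arntl, a core gene of the circadian clock also known as Bmal1, had the most gained MED1 regions, 16 of its 30 assigned regions, with 1 lost. Ahnak had 13 gained of 25, Tenm4 12 of 32, Etv6, an ETS family repressor, 11 of 19, and Myo1e 11 of 24. The most lost regions lay at Tfap2c, a transcription factor gene of the trophectoderm and germ line, with 10 lost of 24 and 2 gained. Myo10 had 7 lost of 30, Esrrb, a transcription factor gene of naive pluripotency, 7 of 32, Zfp607b 6 of 15 and Amotl2 6 of 16.

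The highest ranked gained MED1 region lay inside Nell2 on chromosome 15 (95275468 to 95277448, mm10) and stood at the 100th percentile of the authors' peak p-values in both 2 h libraries. The next were 1.591 kb from Ankrd12 (chromosome 17, 65959027 to 65964111), on chromosome 2 (147743908 to 147745702) with no gene within 100 kb, at an end of Itgam (chromosome 7, 128118367 to 128120422) and 94.68 kb from Sgcz (chromosome 8, 38756386 to 38757935). All 5 were also gained in MED24. The highest ranked lost MED1 regions lay on chromosome 6 (31895869 to 31898173) with no gene within 100 kb, inside Oc90 (chromosome 15, 65895636 to 65897629) and Ninl (chromosome 2, 150947122 to 150949158), 31.77 kb from Lgi1 (chromosome 19, 38340710 to 38342281) and 7.516 kb from Cryz (chromosome 3, 154630699 to 154632166). None of these 5 was lost in MED24 by the same rule, although each was called there in some library.

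MED24 gave 10574 gained, 5839 lost and 21529 retained regions among 66123. Arntl again had the most gained regions, 15 of 34, followed by Gse1 with 13 of 47, Tenm4 with 12 of 30, Camta1 with 11 of 33 and Med13l, which encodes a Mediator kinase module subunit, with 10 of 25. The most lost MED24 regions lay at Arid5b with 12 of 46, and at Nubpl (9 of 18), Frmd4b (9 of 25), Esrrb (9 of 29) and Ptprg (9 of 33). Among the highest ranked gained MED24 regions were those 24.167 kb from Tbk1 (chromosome 10, 121520223 to 121522287), 7.471 kb from Brpf3 (chromosome 17, 28792509 to 28793654), on chromosome 18 (83894678 to 83896031) far from any gene, and 1.836 kb from Ankrd12. The highest ranked lost MED24 regions lay inside Ccdc57 (chromosome 11, 120850302 to 120852887), Flt3 (chromosome 5, 147379310 to 147380079), Ppp2r2c (chromosome 5, 36938710 to 36939669) and Arhgef10l (chromosome 4, 140639346 to 140641376), and 1.971 kb from Mettl5 (chromosome 2, 69888606 to 69889727). Of these 5, only the Flt3 region was not also lost in MED1.

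The 4 libraries of a protein can be split into 2 pairs in 3 ways, and no split other than that by time gave such numbers. Clone b against clone a gave 765 and 627 regions for MED1 and 663 and 510 for MED24, and the crossed split gave 531 and 936 for MED1 and 307 and 1051 for MED24. With the 10000 highest ranked peaks of each library, so that all lists were equally long, 3405 MED1 regions were gained and 2545 lost, against 111 and 120 between the clones. The MED24 numbers were then 3500 gained and 3124 lost, against 95 and 116 between the clones. The excess of gained over lost regions was thus 2.55 to 1 for MED1 with all peaks and 1.34 to 1 with equal lists, and 1.81 to 1 and 1.12 to 1 for MED24. On the log2 scale the ratio with all peaks was 1.35 for MED1, but 0.50 without clone b, 0.57 or 0.44 without the 0 h library of clone a or b and 0.72 with the replicate block. For MED24 it was 0.86, but 0.057 without clone b and 0.13 without the 0 h library of clone b. Because gained and lost regions had to be called in both clones, the counts rose where fewer libraries decided. Counted within each clone and averaged over the pairing (the replicate block), there were 19038 gained and 11565 lost MED1 regions, and 18140 and 12456 MED24 regions. Without the MED1 2 h library of clone a there were 18006 gained MED1 regions, and without the 0 h library of clone a or b there were 8839 or 9428 lost ones. For MED24 the corresponding numbers were 17861 gained, and 9008 or 10979 lost.

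**Figure D1:**
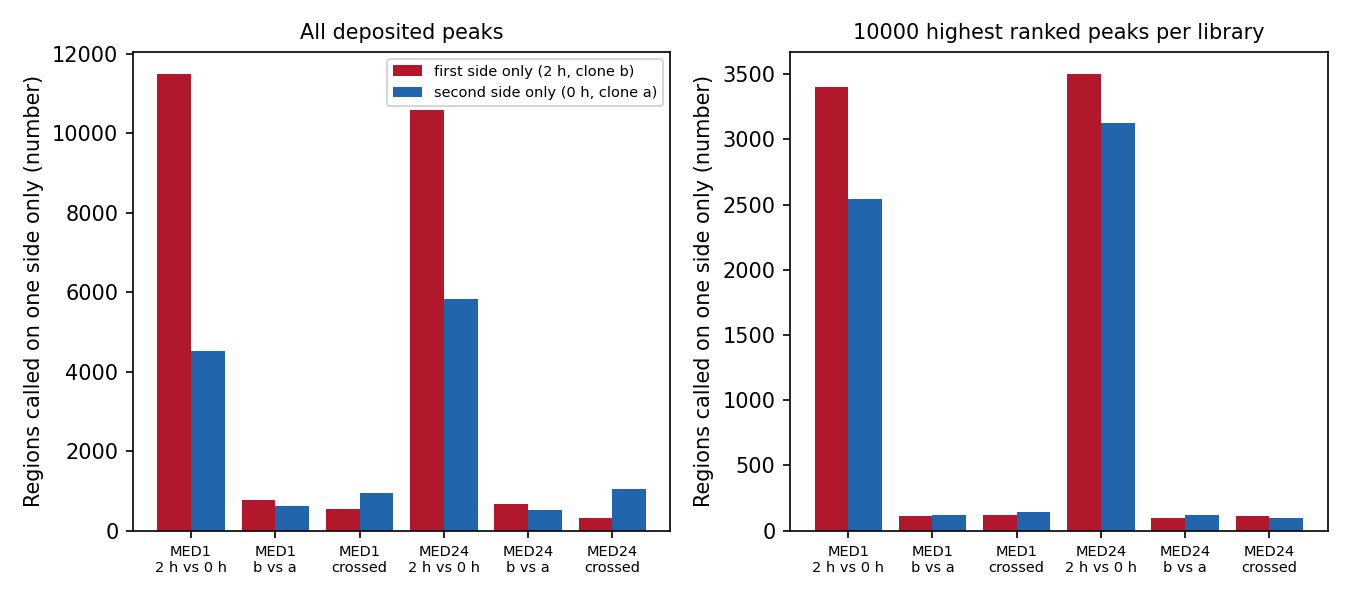
Number of regions (vertical axis, linear, from 0) called in both libraries of one side and in neither of the other, for the 3 splits of the 4 MED1 or MED24 libraries, with all deposited peaks on the left and equally long lists on the right. The split by time gave 11484 and 4508 MED1 regions with all peaks, against at most 936 on one side of another split.

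MED1 and MED24 were compared over 49221 regions called in at least 1 library of both. Of 10036 such regions gained in MED1, 7065 (70.4%) were also gained in MED24, with an odds ratio of 35.3 in a two-sided Fisher's exact test. Of 3736 lost in MED1, 1976 (52.9%) were also lost in MED24, with an odds ratio of 24.3. Independent lists would share 1945 gained and 303 lost regions. Opposite calls were few: 7 regions were gained in MED1 and lost in MED24, and 12 the reverse. The proteins were precipitated from the same clones and times. For changes in the same direction, the splits by clone and across also gave odds ratios above 1, from 6.01 to 10.7, on 13 to 48 shared regions. For opposite directions those splits gave odds ratios from 1.29 to 4.59, on 3 to 14 shared regions. The split by time gave 0.00617 and 0.0122 there. Regions are not replicates, so these tests measure counting error over regions.

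Genes of the naive pluripotency list and genes of the ERK feedback list moved in opposite directions. Regions at the 15 naive pluripotency genes fell: 24 MED1 regions were gained and 39 lost of 219, a net change of -6.85% where random gene lists with as many regions had a median of 11.4% (permutation test, adjusted p = 0.00933). In MED24 22 were gained and 35 lost of 208, a net change of -6.25% against 7.29% (permutation adjusted p = 0.0343). Regions at the 17 ERK feedback genes rose. Most of these genes encode phosphatases, Sprouty and Spred proteins or ETS factors induced by ERK, and Phlda1 and Errfi1 are also among them. In MED1 57 regions were gained and 5 lost of 194, a net change of 26.8% against 10.8% (permutation adjusted p = 0.00933). In MED24 50 were gained and 6 lost of 185, a net change of 23.8% against 7.51% (permutation adjusted p = 0.00933). Adjusted over the lists of one protein alone, p was 0.0063 for both lists in MED1, and 0.0343 and 0.0140 in MED24. Random lists redraw genes while the libraries stay fixed, so permutation p-values of lists measure spread over genes, not between clones.

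Among the naive pluripotency genes, 9 of 15 had more lost than gained regions in each protein, and 3 (MED1) or 4 (MED24) had more gained. Esrrb lost 7 MED1 and 9 MED24 regions and gained 2 and 4. Tfcp2l1 lost 4 MED1 and 3 MED24 regions and gained none. Zfp42, also known as Rex1, went the other way, with 5 regions gained in each protein and 1 lost in MED1, as did Klf5, with 5 and 4 gained and 1 and 2 lost. Nr0b1 and Gbx2 had no gained or lost region in either protein. Among the ERK feedback genes, 15 of 17 in MED1 and 13 in MED24 had more gained than lost regions. Phlda1 gained 10 of 20 MED1 and 9 of 18 MED24 regions, and Dusp5, a nuclear ERK phosphatase gene, 9 of 17 and 8 of 15. Spry4 gained 8 of 24 and 6 of 17, and Errfi1, which encodes an inhibitor of the EGF receptor, 3 of 9 and 5 of 8; none of these 4 genes lost a region. The MED24 call for naive pluripotency missed the threshold with clone b or clone a alone (permutation adjusted p = 0.0756 and 0.0749) and without the 0 h library of clone a or b (permutation adjusted p = 0.0588 and 0.0994), although the difference from random lists, -13.5 points with all libraries, was then -17.7, -17.3, -14.9 and -14.5. The ERK feedback call was lost in both proteins with assignment within 20 kb (difference 12.8 points in MED1 and 8.84 in MED24, permutation adjusted p = 0.147 and 0.366) and in MED1 with a −log10 q of at least 10 (13.7 points, p = 0.147) or 10000 peaks per library (14.3 points, p = 0.418). Both MED24 calls were lost with summit windows (-11.5 and 12.1 points, permutation adjusted p = 0.0581), and all 4 calls with 20000 peaks per library. With 20000 peaks the differences were no smaller, at -24.2 points against -18.3 (MED1) and -15.2 against -13.5 (MED24) for naive pluripotency, and 18.1 against 16.0 and 19.6 against 16.3 for ERK feedback (permutation adjusted p from 0.0504 to 0.169). Leaving out 1 gene at a time ended the MED24 naive pluripotency call for 6 of 15 genes (permutation adjusted p up to 0.126, without Esrrb) and the ERK feedback call for Phlda1 and Dusp5 in each protein (up to 0.0644 in MED1 and 0.0784 in MED24), while the MED1 naive pluripotency call passed without any 1 gene (up to 0.00933).

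**Figure D2:**
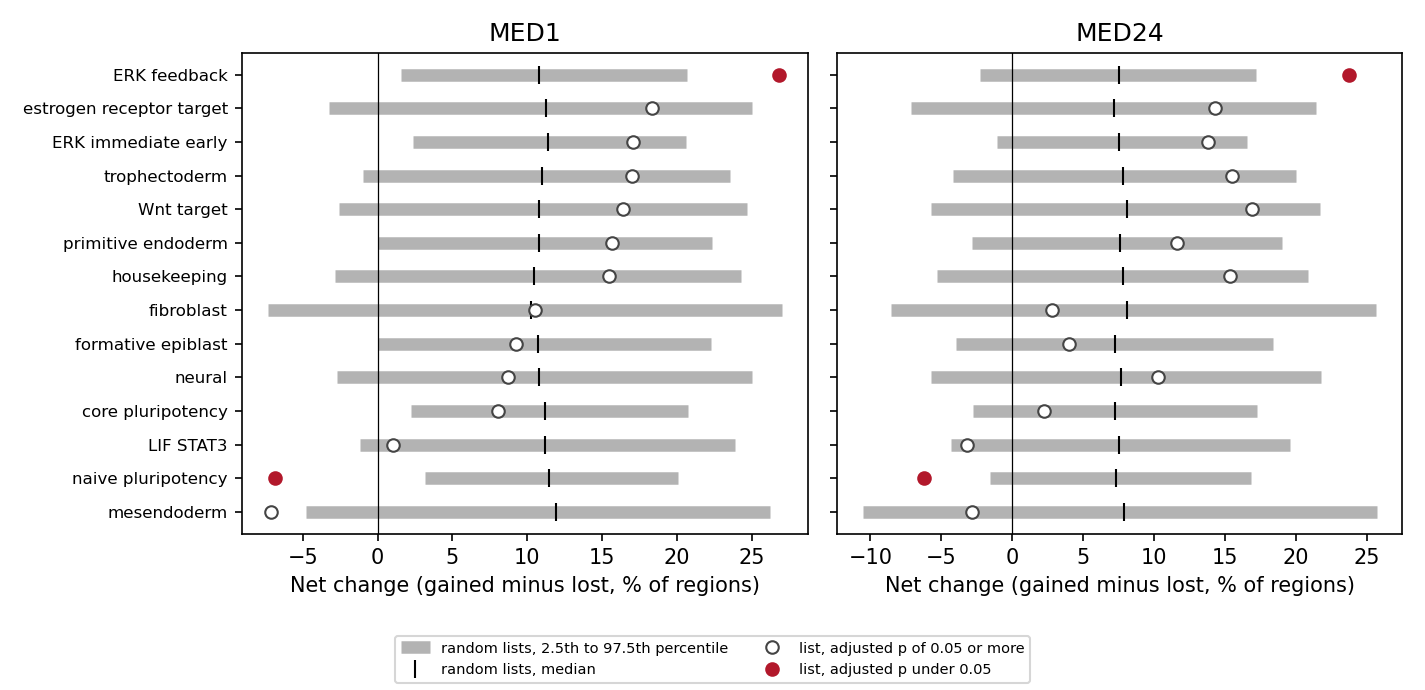
Net change (gained minus lost regions, as a percentage of the regions assigned to a list's genes, horizontal axis) for the 14 gene lists in MED1 and MED24, beside the central 95% range of 10000 random gene lists. Naive pluripotency, at -6.85% in MED1, lies below the random range and ERK feedback, at 26.8%, above it, and both lie outside it in MED24 too.

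The other 12 lists did not pass the threshold in either protein. Their net changes are to be read against random lists, whose medians ran from 10.3% to 11.9% in MED1 and from 7.14% to 8.11% in MED24. Primitive endoderm genes, markers of the lineage that ERK signalling favours in the blastocyst, had 23 MED1 regions gained and 7 lost of 102 (permutation adjusted p = 0.597) and 22 and 10 of 103 in MED24 (permutation adjusted p = 0.616). Sparc had 5 regions gained and none lost in each protein, Cubn 3 and 4 gained, Col4a1 5 and 4 gained and 2 lost in each, while Gata6 had 1 assigned MED1 region, neither gained nor lost, and 2 MED24 regions, 1 of them lost. ERK immediate early genes had 38 gained and 10 lost of 164 in MED1 and 38 and 14 of 174 in MED24 (permutation adjusted p = 0.544 in each). Klf6 had 8 gained and 1 lost in each protein, Myc 5 and 4 gained, Ier5 4 gained in each and Klf10 3 in each, while Fos had 1 gained in each and 3 and 4 lost. For core pluripotency genes the net change was 8.04% in MED1 and 2.22% in MED24, with Jarid2 at 7 and 6 gained and 1 and 5 lost. Formative epiblast genes stood at 9.24% and 3.97%, with Grhl2 at 5 and 6 gained and Foxd3 at 3 and 5 lost. Mesendoderm genes stood at -7.14% and -2.86%, with Gsc at 2 lost in each, and the MED1 value had an unadjusted permutation p of 0.0299 (adjusted 0.167).

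Neural genes had a net change of 8.70% in MED1 and 10.3% in MED24, with Dlx2 at 4 gained in each. Trophectoderm genes stood at 17.0% and 15.5%; Tfap2c had 10 and 4 lost, while Gata3 had 5 and 2 gained and Krt18 3 and 4 gained. Fibroblast genes, markers of another cell type that a culture could hold, stood at 10.5% and 2.78% over 38 and 36 regions, with Twist1 at 2 and 1 gained. Wnt targets stood at 16.4% and 16.9%, with Tcf7 at 4 and Lgr5 at 3 gained in each. Targets of LIF and STAT3 stood at 1.06% and -3.16%, with Socs3 at 4 and 3 lost and Spp1 at 3 lost in each. Lifr went the other way, with 4 gained in each and 1 and 2 lost. In each protein 5 members of that list had more gained and 4 more lost regions. Estrogen receptor targets, listed because 4OHT also binds the endogenous receptor, stood at 18.3% and 14.3% (permutation adjusted p = 0.586 and 0.597), with Greb1 at 2 and 1 gained. Housekeeping genes stood at 15.5% and 15.4%, of which Ywhaz gave 7 and 8 gained regions and no lost one.

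Among regions called in all 4 libraries, strength was compared as the percentile of a region within its library. Naive pluripotency regions fell by a mean of 17.8 percentile points in MED24 over 65 regions (permutation adjusted p = 0.0056), with 44 regions lower in both clones and 10 higher. Random lists had a median of -2.64 points there, and the median shift over the 65 regions was -10.4. Random lists were matched on the number of regions, not on rank at 0 h. The MED1 value was -10.9 points over 57 regions, against 0.396 for random lists, with 34 lower in both clones and 10 higher. It did not pass (permutation adjusted p = 0.108). For Tfcp2l1 the mean over its retained regions was -42.7 points in MED1 and -49.8 in MED24, and for Fgf4 -26.2 and -30.0. ERK feedback regions stood at 9.87 points in MED1 and 7.80 in MED24, against 0.134 and -1.45 for random lists. Neither was past the threshold (permutation adjusted p = 0.147 and 0.259). Phlda1 stood at 60.0 and 41.5 points. No other list passed in either protein. With the median over regions in place of the mean, the MED24 call for naive pluripotency was lost (permutation adjusted p = 0.119), and without clone a the MED1 list passed (permutation adjusted p = 0.0434).

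The single retained regions that moved up most in MED1 lay inside Plcd3 (chromosome 11, 103093756 to 103095753; 93.9 points in clone a and 98.8 in clone b), 8.39 kb from Eps8l2 (chromosome 7, 141371411 to 141374093), inside Angpt2, 41.117 kb from Map4k4 and at an end of Cavin1. Among those that moved down most were regions 18.771 kb from Mamdc2 (chromosome 19, 23467269 to 23468617; -92.8 and -94.3 points), 77.566 kb from Bmper, 44.411 kb from Lpp and at an end of Stat3 (chromosome 11, 100938819 to 100940299; -85.0 and -86.5 points), the transcription factor gene of the LIF pathway. In MED24 the upward moves lay 28.137 kb from Noct (chromosome 3, 51195133 to 51196309; 96.6 and 98.3 points), at ends of Txndc2 and Slc46a3, 13.671 kb from Sub1 and on chromosome 9 (61267280 to 61268814) far from any gene. The downward moves lay 2.563 kb from Hoxc13 (chromosome 15, 102931378 to 102932266; -97.3 and -95.7 points), at an end of Gm30599, 43.13 kb from Nabp1, 1.432 kb from Misp3 and on chromosome 13 (44085418 to 44086852). Across the 20152 MED1 regions the shifts of clones a and b correlated with Pearson's r = 0.647 (Spearman's rho 0.513), and across the 21529 MED24 regions with r = 0.713 (rho 0.634). The difference between clones at 0 h and that at 2 h, each between libraries of 1 time, correlated with r = -0.00505 for MED1 and -0.00686 for MED24. This gave no sign of a clone difference that lasted from 0 h to 2 h, so the pairing rests on the labels. Regions are not independent replicates, and ranks within a library show no absolute change.

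Gained and lost regions lay mostly away from gene ends. Of retained regions, 46.8% (MED1) and 40.9% (MED24) lay within 1 kb of an end of a protein-coding gene. Gained MED1 regions lay there in 6.85% of cases and lost ones in 9.05%, an odds ratio of 0.739 (two-sided Fisher's exact test, p = 3.27e-06). For MED24 the direction was opposite, with 10.6% of gained and 5.94% of lost regions at gene ends, an odds ratio of 1.88 (two-sided Fisher's exact test, p = 5.09e-25). Regions are not replicates, so both p-values measure counting error over regions only. With the 20000 highest ranked peaks per library the log2 odds were -1.72 for MED1 and 0.34 for MED24, against -0.44 and 0.91 with all peaks. Inside genes lay 45.3% of gained and 39.4% of lost MED1 regions. The gene table gives spans without strand, so starts and ends of genes were not told apart.

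**Figure D3:**
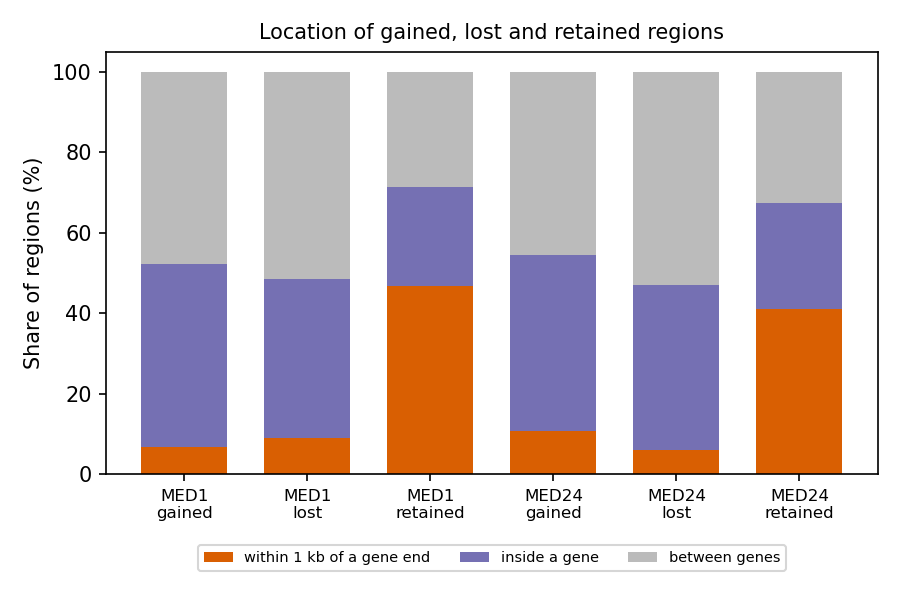
Share of gained, lost and retained regions (vertical axis, percent, from 0) within 1 kb of a gene end, inside a gene or between genes, for MED1 and MED24. Retained regions lie at gene ends in 46.8% (MED1) and 40.9% (MED24) of cases, gained and lost regions in 5.94% to 10.6%.

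The 200 clusters with the most covered bases, made by joining neighbouring regions, held 3971 MED1 and 3579 MED24 regions. Gained regions were less frequent inside them than elsewhere, at 12.3% against 17.9% for MED1 (odds ratio 0.641, two-sided Fisher's exact test, p = 4.41e-21) and 12.4% against 16.2% for MED24 (odds ratio 0.731, p = 4.9e-10). Clusters were chosen by covered bases. Retained regions were wider than gained ones, at a median of 956 against 427 bp (MED1) and 835 against 423 bp (MED24). That choice favours clusters rich in retained regions, so part of the difference may be built in. Lost regions were also narrow (427 and 393 bp). Regions are not replicates, so the p-values for clusters measure counting error over regions. Lost MED1 regions were 6.77% inside and 6.91% elsewhere (odds ratio 0.978, Fisher's exact test, p = 0.771). Lost MED24 regions were 7.88% and 8.88% (odds ratio 0.877, Fisher's exact test, p = 0.0394), a difference that was not past the threshold with joining within 5 kb (p = 0.18) or with clone b (p = 0.178) or clone a (p = 0.12) alone. The largest MED1 cluster spanned 154.755 kb at Dlgap1 and Tgif1 (chromosome 17, 70719902 to 70874656) with 7 gained and 3 lost of 39 regions. A histone gene cluster on chromosome 13 (23488702 to 23598229) had 1 gained and 2 lost of 27. The cluster at Trim71 on chromosome 9 (114488889 to 114586273) had 10 gained and none lost of 47. A cluster on chromosome 8 (84893417 to 85041663) that overlapped Klf1, Junb and many other genes had none gained and 3 lost of 30. No MED1 region was assigned to Junb itself. The cluster at Cd9 on chromosome 6 (125409272 to 125505312) had 5 gained and 2 lost of 46. In MED24 the same histone genes led with none gained and 2 lost of 26 regions. Next came clusters at Lmna and its neighbours (5 gained and 3 lost of 32) and at Junb and many other genes (1 gained of 24). Those at Sall1 (5 gained and 5 lost of 33) and Ptma (1 gained and 1 lost of 23) followed. The 1 MED24 region assigned to Junb itself was neither gained nor lost.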

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

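Equally long lists and the list of estrogen receptor targets were planned before the data were examined, but their use here as tests of an explanation, the comparison of the ratio of 8.72 with that for MED1, the shares and percentiles of regions and the adjustment of the tests with a gene left out or relative to mean rank were chosen only after the result was seen; the other tests in this part were set out before their values were seen.

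The share of changed regions at gene ends differed in direction between MED1 and MED24 in each clone. The odds ratio of a gene end, gained against lost, was 0.701 in clone a and 0.808 in clone b for MED1, and 1.54 and 1.69 for MED24. The difference between the proteins was not itself tested.

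That pattern did not come from longer peak lists at 2 h as a whole, since with the 20000 highest ranked peaks per library the log2 odds were -1.72 for MED1 and 0.34 for MED24, against -0.44 and 0.91 with all peaks, so the sizes moved with list length while the directions did not. Nor did it rest on regions that the other protein called in all 4 libraries: without them the log2 odds were 0.75 for MED24 and -0.47 for MED1. Of the MED24 regions gained at gene ends, both 0 h MED1 libraries called 22.5%, against 2.58% elsewhere, a ratio of 8.72, where the ratio for MED1 regions gained and MED24 at 0 h was 1.85. A candidate explanation for part of the MED24 side is therefore that MED24 lists at 0 h missed gene ends that MED1 lists already held. The 2 sets also differ in precipitation (MED24 through FLAG), in list layout and in the column used for ranking. Peak names in the MED24 lists, moreover, carry a folder name of EP300. These differences cannot be told apart from a real difference between the subunits, which stays open and was not tested.

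Different numbers of peaks per library do not account for the many regions gained and lost at 2 h in both clones, since with 10000 peaks per library the split by time gave at least 23.0 times as many regions as the larger other split, and with 20000 peaks 10019 against 492 in MED1 and 10589 against 509 in MED24. Weak regions crossing the calling threshold stay open, more so for lost regions, since the other splits had no region among the 10000 highest ranked on one side and missing from the other, and a few regions could pass the bound set in advance, a ratio to those splits. Such regions were 2054 (17.9%) of gained and 198 (4.39%) of lost MED1 regions and 1760 (16.6%) and 521 (8.92%) in MED24, against 23.9%, 28.8%, 23.3% and 26.6% of all regions called in both libraries of that side, and the median percentile was 51.4 and 35.6 in MED1 and 47.7 and 39.6 in MED24. Whether 4OHT acted apart from RAF cannot be told apart from ERK activation, because every treated library had both; the estrogen receptor targets did not pass the threshold (adjusted p 0.586 and 0.597 for net change, 0.684 and 0.384 for rank shift, which was 12.1 points in MED24), which excludes nothing. With equally long lists the near balance of gained and lost regions is largely set by the list length, so the excess of gained over lost regions stays open.

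Regions near naive pluripotency genes were more often lost than gained, 39 against 24 of 219 in MED1 and 35 against 22 of 208 in MED24. Regions near ERK feedback genes were more often gained than lost, 57 against 5 of 194 in MED1 and 50 against 6 of 185 in MED24. Most regions of either list were thus neither lost nor gained. Relative to regions of the same mean rank over the 4 libraries, both lists stayed apart from random lists in both proteins. The larger unadjusted permutation p was 0.0071 (adjusted 0.0497) for naive pluripotency and 0.0013 (adjusted 0.0121) for ERK feedback. That mean rank therefore does not account for the whole pattern. It takes in the 2 h libraries and ranks an uncalled library lowest, so it contains the calls themselves. Whether region strength at 0 h accounts for the pattern cannot be told from it. No single gene gave the whole of a list's difference: the weakest cases had an unadjusted permutation p of 0.018 for naive pluripotency (MED24 without Esrrb, difference from random lists -11.9 points against -13.5 with it) and 0.0112 for ERK feedback (MED24 without Phlda1, 13.3 against 16.3), but the adjusted p was then 0.126 and 0.0784, so these calls were lost. A response of these genes to ERK activation, the treatment the design names, is a hypothesis that remains, beside 4OHT itself. The ERK feedback call was lost with assignment within 20 kb, where the difference from random lists was 12.8 points in MED1 and 8.84 in MED24.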

How the results depend on the processing

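The assignment to the nearest gene end, and leaving out a clone for the overlap of the proteins, location and clusters, were chosen only after the result was seen; the other alternatives were fixed before. Depth is unknown and each group holds 2 clones, so no alternative tests the clones' own spread. The planned motif alternatives were not run, for lack of a genome sequence here. Of the values that answer a comparison, 120 alternatives stayed on the same side of the threshold, within 1.5 times for counts, or, for values with no test, within the SD between clones, while 49 moved further, 3 were no longer past the threshold and 2 changed sign; those of the overlap of MED1 and MED24, gene ends and gained regions in clusters all stayed on the same side. Peak number differences stayed within that SD. For leaving out a library this was fixed in advance, since each group holds 2 libraries, so these cases, counted among the 120, show no stability. The MED24 difference ran from 2401.5 to 8887.5 without a library. In the text below the cause of a change was not tested unless the setting itself uses fewer peaks or libraries. Of 17 alternatives, the naive pluripotency net change passed in 16 for MED1 (adjusted p up to 0.0504) and 11 for MED24 (up to 0.169), and ERK feedback in 13 for MED1 (up to 0.418) and 14 for MED24 (up to 0.366), each with its direction kept.

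Fewer peaks gave fewer regions. With a −log10 q of at least 10, 2708 MED1 regions were lost. With the 10000 highest ranked peaks, 3405 MED1 regions were gained and 2545 lost (log2 ratio 0.42), and 3500 and 3124 in MED24 (0.16). With 20000, 5847 MED1 regions (log2 ratio 0.49) and 5631 MED24 regions were gained. With the replicate block, that is within each clone, 19038 MED1 regions were gained and 11565 lost (log2 ratio 0.72), and 18140 and 12456 in MED24; the pairing changed no call of a list. Leaving out clones or libraries gave 12796 to 20564 gained and 5886 to 12382 lost MED1 regions (log2 ratio 0.44 to 1.61), and 11979 to 21140 gained and 6884 to 14552 lost MED24 regions (0.0571 to 1.38). The log2 odds of lost regions in large clusters were 0.0662 for MED1 and -0.176 for MED24 with joining within 5 kb, and -0.00477 to 0.0224 and -0.0950 to -0.0946 without a clone.

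The number of lists past the threshold for net change was 1 in MED1 with a −log10 q of at least 10, with the 10000 highest ranked peaks and within 20 kb, and 0 with 20000; in MED24 it was 0 with 20000 and with summit windows, 1 within 20 kb and 1 to 2 without a clone or library. For the rank shift it was 1 in MED1 by fold, and 0 to 1 without a clone; in MED24 it was 2 within 20 kb and 0 by the median. Lists not past the threshold otherwise passed for MED24 LIF STAT3 with a cover of 50% (adjusted p 0.00728), MED24 trophectoderm with every gene within 50 kb (0.0437), the MED24 rank shift of primitive endoderm within 20 kb (0.0490) and the MED1 rank shift of naive pluripotency by fold (0.0140) and without clone a (0.0434).

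Among lists, signs changed in 43 cases, all for lists not past the threshold before or after (lowest adjusted p 0.28). The values are differences from random lists. With a −log10 q of at least 10 they were -3.51 (primitive endoderm), 4.997 (formative epiblast) and -4.76 (fibroblast) in MED1, and 6.94 (formative epiblast), -6.65 (neural) and -6.45 (estrogen receptor target) in MED24. With 10000 peaks they were 44.4 (MED1 neural) and 11.1 (MED24 fibroblast), and with 20000 peaks 5 (formative epiblast) and -13.3 (fibroblast) in MED1 and 3.64 (formative epiblast) in MED24. Summit windows gave 0.708 (formative epiblast) and -2.94 (fibroblast) in MED1, and a cover of 50% gave 1.20 (MED1 formative epiblast). Within 20 kb the net change was -1.85 (MED1 ERK immediate early), 3.18 (MED24 formative epiblast) and 1.11 (MED24 fibroblast), and with every gene within 50 kb -1.36 (MED1 housekeeping), 0.320 (MED24 mesendoderm), 9.32 (MED24 fibroblast) and -0.177 (MED24 housekeeping). Without a clone or library the MED1 net change ran from -7.76 to 11.2 (trophectoderm) and from -2.77 to 5.74 (fibroblast). For the rank shift, within 20 kb gave 1.33 (formative epiblast) and 4.17 (mesendoderm) in MED1 and 5.05 (mesendoderm) and 11.5 (neural) in MED24. Fold or length gave 1.01 (formative epiblast), 0.171 (mesendoderm) and -0.343 (housekeeping) in MED1 and 0.525 (fibroblast) in MED24. The median gave -2.37 (primitive endoderm), 3.15 (formative epiblast), -3.55 (estrogen receptor target) and -0.0949 (housekeeping) in MED1 and 1.55 (formative epiblast) in MED24. Without a clone the shift ran from -1.89 to 0.893 (mesendoderm), -1.77 to 4.86 (trophectoderm), -1.74 to 2.65 (housekeeping) and -1.07 to 0.495 (formative epiblast) in MED1, and from -8.89 to 5.01 (neural) in MED24.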

Other observations

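The tests of gene families in this part were chosen after the main results were seen, and those of crowding and of neighbouring keratin genes were set out before their values were seen.

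Keratin genes, which encode the intermediate filaments of epithelia, had more gained regions than random lists when pooled as a family, in MED24 mainly on chromosome 15. Genes were grouped by the letters before the first digit of their symbol, giving 124 families in MED1 and 131 in MED24. The keratin family was the only family past the threshold in either protein, with 28 MED1 regions gained and none lost of 54, a net change of 51.9% where random lists had a median of 9.26% (permutation adjusted p = 0.0127). In MED24 27 were gained and 4 lost of 65, a net change of 35.4% against 7.58% (permutation adjusted p = 0.0127). Krt80 had 5 gained regions in each protein, Krt8 3 in each and Krt18 3 and 4, on chromosome 15. No keratin gene on that chromosome lost a region in either protein. On chromosome 11, Krt23 had 2 gained in each, and Krt42 had 1 gained in each and 3 lost in MED24. Krt24, also on chromosome 11, lost 1 MED24 region. At the chromosome 11 genes few MED24 regions were gained, and all lost ones of the family lay there, so the MED24 excess came mainly from chromosome 15. The chromosomes were not tested apart. Krt7, Krt8 and Krt18 also stand in the trophectoderm list. Keratin genes lie side by side, so the same genes were moved together along the ordered genes: a share of at most 0.000125 of all shifts gave a net change as high in either protein. A change of the keratin loci with treatment is a hypothesis found and tested on the same data.

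Gained regions crowded at the same genes. In MED1 245 genes had at least 5 gained regions, where 1000 shuffles of gained regions over all assigned regions gave 132 to 167 (central 95%), and in MED24 173 genes did, against 102 to 135. For lost regions 20 genes did in MED1 and 45 in MED24, against medians of 7 and 16 in the shuffles. Chance placement over the regions of each gene is not enough to account for this, and nearby regions that change together could be 1 candidate source, not tested here.

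The X chromosome had the highest share of lost regions of any chromosome, 118 of 1311 MED1 and 180 of 1439 MED24 regions, while chromosome 19 had the highest log2 ratio of gained to lost regions among chromosomes 1 to 19 and X, 1.79 in MED1 and 1.14 in MED24. These values were not tested. Few regions were called throughout for one protein and never for the other: 375 in all 4 MED1 and no MED24 library, and 770 in all 4 MED24 and no MED1 library, of 78166.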
